A study of Mus musculus with 6 samples.

How the data were processed

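Total RNA of mouse skin was sequenced in 6 libraries, 3 from mice under chronic restraint stress (CRS) and 3 from control mice (CON), taken after 12 weeks. The study's design describes 3 mice per group, so each library was taken as 1 mouse, which Xist beside Y-linked genes leaves in doubt for CON replicate 1. Sex, age, strain and body site were not given in the sources used here. RNA was isolated with Trizol and 1 µg went into each Illumina library, per the labels' protocols. Strand, read length and poly(A) selection were not given there, so fragments of overlapping genes on opposite strands may have been counted together.

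The deposited values were FPKM (fragments scaled by exon length and by library size), 1 file per library with 54146 Ensembl gene IDs, and the authors' processing had ended there. Reads were aligned with HISAT2 to the mouse build GRCm39, per the submitters' processing notes. The counting program, the annotation and the versions were not given in the sources used here. Gene symbols, types and merged exon lengths came from GENCODE M21, an annotation of the older build GRCm38, which held 54079 of the IDs. The gene lengths implied by the files matched that annotation, and not only its IDs, so the build behind the counting is open and no coordinates are given.

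In each file, FPKM multiplied by merged exon length fell on whole multiples of 1 step. Of the values up to 100 fragments, between 98.1% and 98.3% per library lay within 0.05 of a whole number. The steps gave a depth of 13.3 to 25.7 M fragments per library. Low values rest on few fragments: a gene of 3536 nt at 1.40 FPKM, as Mir17hg in CRS replicate 1, corresponds to 95 fragments. These recovered fragments served to judge depth and for 1 added alternative. The units stayed FPKM, so no count test was used as the main one.

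Genes with a mean of at least 0.1 FPKM over the 6 libraries were tested, 28389 in all. The low filter was chosen because the study concerns a long non-coding RNA. Values entered as log2(FPKM + 0.1), so fold changes are on that scale and understate the change of low genes. CRS and CON were compared with limma 3.58.1 (R 4.3.3), using moderated statistics with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. An exact two-sided permutation test of 3 against 3 values was computed for each named gene. Its smallest possible p is 0.1, so it cannot pass the threshold.

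Before the data were examined, 36 gene lists were written for skin cell types, pigmentation, TGF-beta, stress hormones and general processes. The Mir17hg cluster list was not tested as a list. The other 35 were tested with limma's camera at a preset inter-gene correlation of 0.01, needing at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. Each was also run with an estimated correlation and with fry. Camera asks whether a list's genes move more than other genes. The p-value of fry asks whether they move, on balance, one way, and compares them with no other genes.

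The genes named were fixed by a rule written at the same time. It took 10 focus genes, and in each direction the 10 genes with the lowest unadjusted p when fewer than 5 passed the adjusted threshold. Those needed groups that did not overlap, at least 1 FPKM in the higher group, a proper symbol that was not a pseudogene or clone name, and at most 3 genes of 1 symbol root. For each list that passed, the rule took the 4 members with the lowest p in its direction, and for each other list the 2 with the lowest p. Some genes that this rule selected are not reported here. Gene families by symbol root, the sex-linked genes per library and the gene length trend were examined after the results were seen.

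The scripts were tested on simulated data drawn with the real means and spreads of the 28389 genes. At adjusted p 0.05, the CRS against CON fit called 4% of 50 genes changed by 1 log2 unit, 42% at 2 units, 86% at 3 units and 98% at 5 units, and 2 unchanged genes. A planted list shifted by 1 log2 unit reached an adjusted p of 2.58e-07, and 0 other lists passed. That simulation drew genes independently, so it holds no correlation between genes.

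The alternatives tried were other pseudocounts, filters, scalings, variance models, array weights, a replicate block, each library left out, other thresholds and other list tests. After the data were seen, 5 more were added: limma voom on the recovered fragments, a correction for gene length and GC content, features of at least 200 nt, both outlying libraries left out, and a skeletal muscle covariate. The length correction smoothed each library's deviation from the gene means over length and GC content by lowess (span 0.3, genes of at least 1 FPKM) and subtracted it. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.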

Results

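Skin of 6 mice was compared by RNA sequencing, 3 under chronic restraint stress (CRS) and 3 controls (CON), after 12 weeks. Chronic restraint, in which an animal is repeatedly confined, is a rodent model of psychological stress. The comparison addresses which skin transcripts differ under such stress. The study's title points to Mir17hg, the long non-coding host transcript of the miR-17-92 microRNA cluster, to the TGF-beta receptor gene Tgfbr2 and to pigment production. Depth, recovered from the FPKM values, was 18.9, 19.9 and 13.3 M fragments in CON replicates 1 to 3 and 19.2, 25.7 and 25.2 M in the CRS replicates.

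In the skin of CRS mice, keratin and keratin-associated genes of the hair shaft, sebaceous gland genes and epidermal differentiation genes were higher as groups. Cell cycle genes, interferon-stimulated genes, skeletal muscle genes and mitochondrial transcripts were lower, and the pigment cell genes were lower by less. These were shifts of whole lists with camera at its preset correlation. That test passed 15 lists for the real groups and 11 to 22 for other splits of the libraries into 3 and 3. Relative to all genes, the muscle value went from -1.81 to -0.83 without CON replicate 1, and the mitochondrial value from -1.19 to -0.25. The pigment cell list lost its call without CON replicate 2 or without CRS replicate 1. No single gene passed the adjusted threshold with limma: 0 genes were higher and 0 were lower. With an estimated correlation 0 of the 35 lists passed, the smallest adjusted p being 0.465.

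Mir17hg stood at 9.89, 3.19 and 2.70 FPKM in CON and 1.40, 6.76 and 0.741 FPKM in CRS, from 66 to 661 fragments per library. Its means were 5.26 ± 4.01 and 2.97 ± 3.30 FPKM (SD, n = 3), and the groups overlapped. The log2 fold change was -1.14 (SE 0.80, limma adjusted p = 0.9999), and it lay at -0.50 without CRS replicate 3 and at -2.01 without CRS replicate 2. The microRNA genes of the cluster were under the filter. Tgfbr2, which encodes the type II TGF-beta receptor, stood at 5.30, 8.16 and 6.88 FPKM in CON and 7.33, 15.1 and 6.36 FPKM in CRS. Its log2 fold change was 0.41 (SE 0.40, limma adjusted p = 0.9999), and it lay at 0.031 without CRS replicate 2, which held the highest value.

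Among the pigment cell genes, Mc1r, the melanocortin receptor of melanocytes, was 5.21 ± 1.74 FPKM in CON and 2.18 ± 0.80 FPKM in CRS (SD, n = 3). Its log2 fold change was -1.22 (SE 0.42). Mlana, a melanosome protein, was 121.9 ± 12.3 and 67.6 ± 25.8 FPKM, a log2 fold change of -0.92 (SE 0.38). Dct, an enzyme of melanin synthesis, was 46.7 ± 4.90 and 30.3 ± 3.54 FPKM, a log2 fold change of -0.62 (SE 0.28). The 3 CRS values lay below the 3 CON values for these genes, where the exact permutation p was 0.1, the smallest the design allows. The other focus genes overlapped between groups: the log2 fold change was -0.59 (SE 0.38) for tyrosinase, Tyr, -0.28 (SE 0.34) for Tyrp1 and -0.21 (SE 0.33) for the melanosome matrix gene Pmel. It was -0.84 (SE 0.65) for the receptor gene Kit and 0.52 (SE 0.43) for Mitf, the transcription factor of the melanocyte lineage. All 10 focus genes had an adjusted p of 0.9999. The median log2 fold change of all genes was -0.20, close to the values of Pmel and Tyrp1. Pmel turned to 0.028 under median-ratio scaling.

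**Figure D1:**
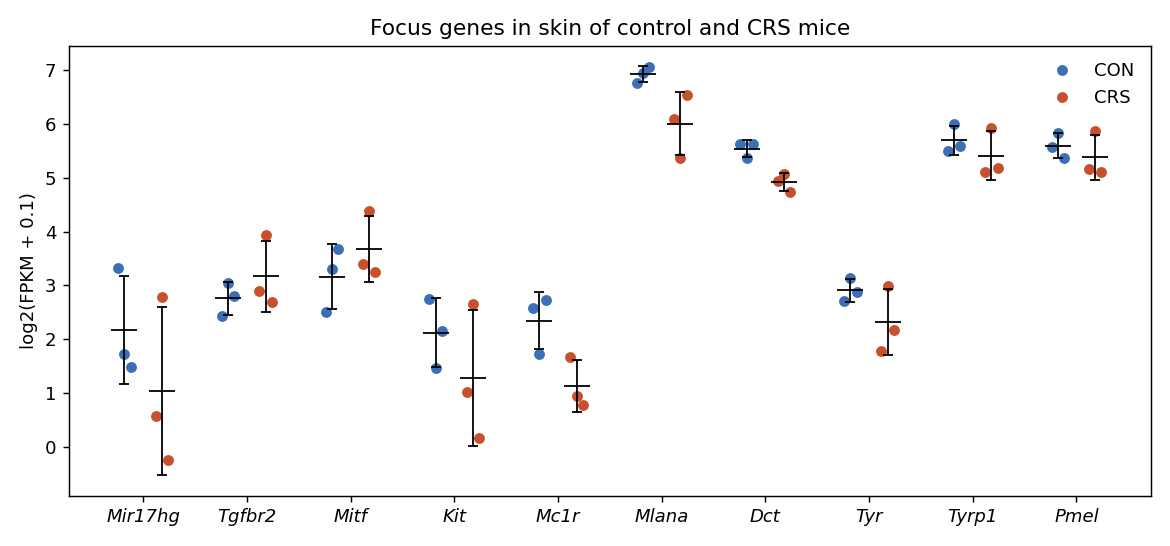
Level of each focus gene as log2(FPKM + 0.1) on the vertical axis in the 3 CON (blue) and 3 CRS (red) libraries; points are mice, horizontal bars the mean and error bars the SD. For Mc1r, Mlana and Dct the CRS points lie below the CON points, and for Mir17hg and Tgfbr2 the groups overlap.

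Of all 28389 genes tested, 19257 had a log2 fold change under 0 and 9132 above 0, the background for the member counts of each list. The melanocyte and melanogenesis list fell as a group, 21 of its 24 measured members being lower in CRS. Its median log2 fold change was -0.40, or -0.20 relative to all genes (camera adjusted p = 0.00686; adjusted p = 0.680 with an estimated correlation). At an unadjusted p under 0.05, 2 members were lower, and 0 passed adjusted over all genes or adjusted over the list alone. The melanosome transporter gene Slc45a2 was 5.52 ± 1.11 FPKM in CON and 3.64 ± 0.38 FPKM in CRS. The call was lost without CON replicate 2 (-0.13 relative to all genes, adjusted p = 0.202) and without CRS replicate 1 (-0.070, adjusted p = 0.643). The value was -0.44 without CRS replicate 2, whose library median lay above those of the CON mice. The list of signals directed at melanocytes did not pass (15 genes, -0.38 relative to all genes, adjusted p = 0.182, ranging from 0.00474 to 0.788 over the alternatives). It passed as lower without CRS replicate 2 (-0.41, adjusted p = 0.00474) and was at -0.16 without CRS replicate 1 (adjusted p = 0.727), the ends of its range with each mouse left out. Its member Kitl, the ligand of Kit, had a log2 fold change of -1.14 (SE 0.56) and Hes1 of -0.83 (SE 0.42).

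The TGF-beta pathway list did not pass (camera adjusted p = 0.865), and the direction of its test was down. Of its 27 members 9 were higher and 18 lower, and its median relative to all genes was 0.041. Its member Pmepa1 had a log2 fold change of -0.70 (SE 0.44). The direction depended on single CRS mice: without CRS replicate 2 the list was lower (-0.43 relative to all genes, adjusted p = 5.07e-05), and without CRS replicate 1 it was at 0.34 (adjusted p = 0.0567). The test also turned without CRS replicate 3 (0.20) and CON replicate 2 (0.13), and over all alternatives the adjusted p ran from 1.14e-05 to 0.991. The list median of CRS replicate 2 was 0.78, while CRS replicates 1 and 3 were at -0.45 and -0.58.

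The hair shaft and inner root sheath list rose, with 29 of 30 members higher and a median log2 fold change of 1.11, or 1.31 relative to all genes (camera adjusted p = 6.37e-22; adjusted p = 0.465 with an estimated correlation). The keratin gene Krt84 was 18.99 ± 13.96 FPKM in CON and 52.9 ± 4.76 FPKM in CRS, and Krtap3-1 was 614 ± 435 and 1685 ± 536 FPKM. Krtap16-1 and Krtap2-4 had log2 fold changes of 1.36 (SE 0.53) and 1.39 (SE 0.57). The CRS library medians lay above all CON medians, although CRS replicate 1 at 0.22 was close to CON replicate 2 at 0.17. Without CON replicate 1 the value was 0.67. The hair matrix and follicle growth regulator list did not pass (15 of 21 lower, -0.23 relative to all genes, adjusted p = 0.0881, ranging from 7.30e-05 to 0.893 over the alternatives). It passed as lower without CRS replicate 2 (-0.57, adjusted p = 0.000848) and without CON replicate 1 (-0.21, adjusted p = 0.0424). The value was -0.018 without CRS replicate 1 (adjusted p = 0.888) and -0.056 without CRS replicate 3 (adjusted p = 0.567). Its members Msx1 and Lef1 had log2 fold changes of -0.76 (SE 0.31) and -0.99 (SE 0.44).

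The interfollicular epidermis list rose as a group, with all 26 fold changes above 0 and a value of 0.73 relative to all genes (camera adjusted p = 6.89e-11; adjusted p = 0.465 with an estimated correlation). Tgm3, a transglutaminase of cornification, had a log2 fold change of 1.22 (SE 0.44), Cnfn of 1.09 (SE 0.51), Sbsn of 0.82 (SE 0.42) and the envelope protein gene Ivl of 0.98 (SE 0.48). The activated keratinocyte list rose as a group, with 15 of 17 fold changes above 0 (0.97 relative to all genes, camera adjusted p = 2.32e-07; adjusted p = 0.643 with an estimated correlation). Its leading members were Krt16, Sprr2h, Sprr1b and Il1a, with log2 fold changes of 1.05, 1.10, 0.87 and 0.85. Without CON replicate 1 the epidermis value was 0.43, and the activated keratinocyte list no longer passed (0.46, adjusted p = 0.0846). Library medians of both lists overlapped between the groups: epidermis was -0.15 in CRS replicate 3 and 0.14 in CON replicate 3, and activated keratinocyte 0.52 in CON replicate 3 and 0.21 in CRS replicate 2.

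The sebaceous gland list rose as a group, with 14 of 15 fold changes above 0, by 0.60 relative to all genes (camera adjusted p = 9.60e-09; adjusted p = 0.465 with an estimated correlation). Awat1, a wax ester synthase, was 9.90 ± 4.37 FPKM in CON and 28.4 ± 9.06 FPKM in CRS. Dgat2l6, Elovl3 and Far2 had log2 fold changes of 1.39 (SE 0.45), 0.82 (SE 0.37) and 1.09 (SE 0.55). The CRS library medians lay above all CON medians.

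Other cell type lists rose with the preset correlation but rested on CON replicate 1. Dermal fibroblast genes were higher in 23 of 24 members (0.66 relative to all genes, adjusted p = 1.73e-09; adjusted p = 0.643 with an estimated correlation), with Fmod at 1.29 ± 0.72 FPKM in CON and 3.10 ± 1.63 FPKM in CRS, and with Fbn1, Pi16 and Col3a1. Without CON replicate 1 the value was 0.16 (adjusted p = 0.251). Macrophage and dendritic cell genes (18 of 20 higher, adjusted p = 3.38e-05; adjusted p = 0.691 with an estimated correlation), led by Itgax, H2-Aa, Lyz2 and H2-Eb1, went to 0.10 without that mouse (adjusted p = 0.749), where the direction of the test turned. T, NK and B cell genes (16 of 19 higher, adjusted p = 0.00015; adjusted p = 0.565 with an estimated correlation), led by Igkc, Ncr1, Cd3g and Cd247, went to 0.18 (adjusted p = 0.212). Mast cell genes (7 of 11 higher, adjusted p = 0.0395; adjusted p = 0.707 with an estimated correlation), led by Cpa3, Cma1, Ms4a2 and Mcpt4, went to 0.0011 (adjusted p = 0.730), and were also lost without CRS replicate 2 (adjusted p = 0.356) or 3 (adjusted p = 0.174). Follicle stem cell and outer root sheath genes passed narrowly (7 of 13 higher, adjusted p = 0.0268; adjusted p = 0.643 with an estimated correlation), with Krt79 at a log2 fold change of 1.11 (SE 0.37) and Krt16, Krt6a and Krt75 at 1.05, 0.52 and 0.60. That call was lost without CON replicate 1 (0.17, adjusted p = 0.317) and without CRS replicate 2 (0.11, adjusted p = 0.354).

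The proliferation list fell, with 25 of 26 cell cycle genes lower and 13 of them at an unadjusted p under 0.05. Its median log2 fold change was -0.81, or -0.62 relative to all genes (camera adjusted p = 1.77e-16; p = 0.0423 and adjusted p = 0.465 with an estimated correlation). The cell cycle kinase gene Cdk1 was 12.4 ± 0.84 FPKM in CON and 6.48 ± 0.70 FPKM in CRS (SD, n = 3). Ube2c was 27.4 ± 2.25 and 13.5 ± 2.14 FPKM, Ccna2 17.9 ± 1.35 and 9.24 ± 2.72 FPKM, and Ccnb2 23.4 ± 0.45 and 13.02 ± 1.69 FPKM. The CRS library medians lay below all CON medians, although CRS replicate 2 at 0.16 was close to CON replicate 2 at 0.30. With each mouse left out in turn the value stayed between -0.77 and -0.42, and the largest camera adjusted p was 3.24e-06. At its preset correlation camera takes genes as nearly independent, so that p is no measure of the spread between mice. With a skeletal muscle covariate, added after the data were seen, the value was -0.29.

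The interferon response list fell as a group, with all 23 fold changes under 0, by -0.46 relative to all genes (camera adjusted p = 5.11e-10; p = 0.0554 and adjusted p = 0.465 with an estimated correlation). Rsad2, an antiviral protein gene, was 3.41 ± 1.39 FPKM in CON and 0.85 ± 0.29 FPKM in CRS. Ifit1, Bst2 and Ifit3 had log2 fold changes of -1.66 (SE 0.50), -0.99 (SE 0.31) and -1.27 (SE 0.43). At an unadjusted p under 0.05, 6 members were lower, and the library medians of the groups did not overlap. With each mouse left out in turn the value stayed between -0.67 and -0.41. The largest camera adjusted p was 0.000175, again at the preset correlation and no measure of the spread between mice.

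The skeletal muscle list fell as a group, with 23 of 24 fold changes under 0, by -1.81 relative to all genes (camera adjusted p = 2.16e-09; adjusted p = 0.665 with an estimated correlation). Pvalb, a calcium-binding protein of fast muscle, stood at 2011, 209.5 and 477.8 FPKM in CON and 32.8, 185.2 and 111.3 FPKM in CRS. Myl1, Tnni2 and Myoz1 had log2 fold changes of -2.11, -2.24 and -2.14. Library medians overlapped, with CON replicate 1 at 2.99 and CRS replicate 1 at -2.16. The value was -0.83 without CON replicate 1 and -1.09 without CRS replicate 1. The list of mitochondrially encoded genes fell as a group, with all 13 fold changes under 0, by -1.19 relative to all genes (camera adjusted p = 1.14e-05; adjusted p = 0.665 with an estimated correlation). They made up 15.3% of the fragments of CON replicate 1 and 2.50% to 4.19% of those of the other libraries. Examples are mt-Atp6, mt-Nd6, mt-Nd2 and mt-Nd4, with log2 fold changes of -2.03, -1.37, -1.57 and -1.41, and without CON replicate 1 the list's value was -0.25. Its call was lost with both outlying libraries, CON replicate 1 and CRS replicate 2, left out (-0.54). Nuclear genes of oxidative phosphorylation passed (27 of 28 lower, -0.13 relative to all genes, adjusted p = 0.0244; adjusted p = 0.812 with an estimated correlation), led by Cox6a2, Sdhc, Sdhd and Cycs. That call was lost without CON replicate 1 (adjusted p = 0.0850), CON replicate 2 (0.202) or CRS replicate 1 (0.144), and the value turned to 0.14 without CRS replicate 2 (0.197).

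**Figure D2:**
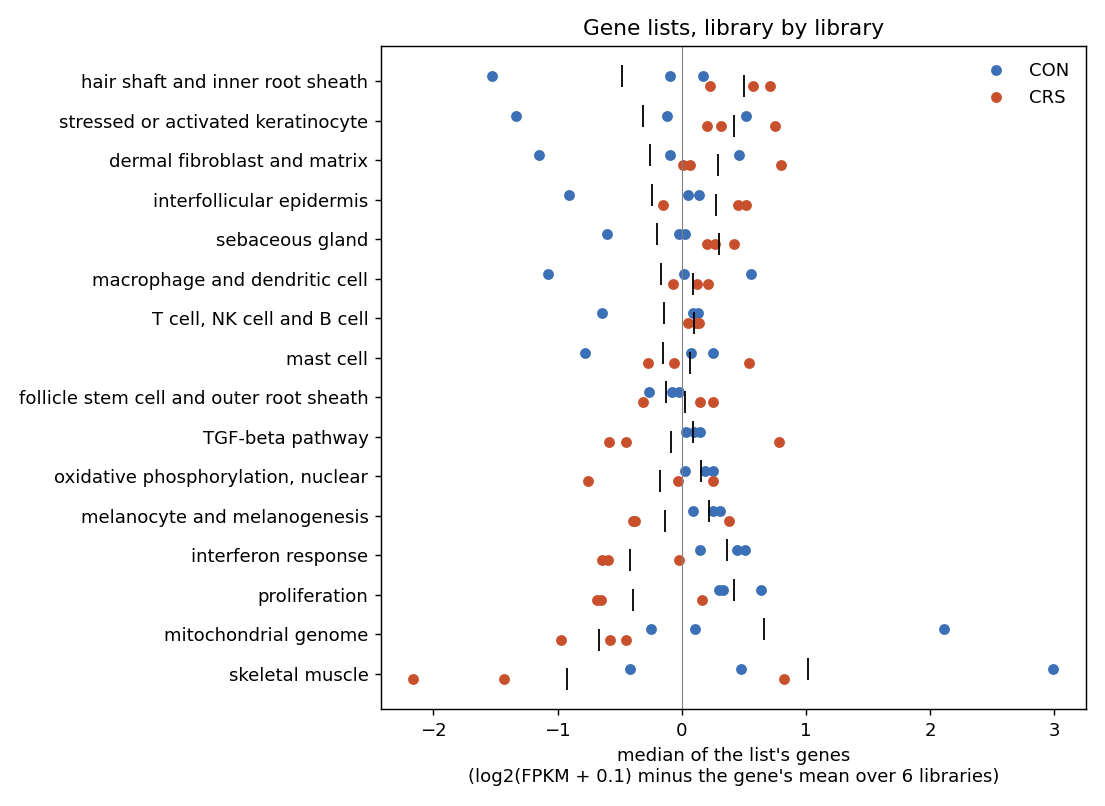
For each list that passed with camera and for the TGF-beta pathway list, points are the 3 CON (blue) and 3 CRS (red) libraries, placed by the median over the list's genes of log2(FPKM + 0.1) minus the gene's mean over the 6 libraries, and black ticks are group means. The points of the groups do not overlap for proliferation, interferon, hair shaft, sebaceous gland and mitochondrial genome. CON replicate 1 is the leftmost CON point of the hair shaft row, at -1.53, and the rightmost of the muscle row, at 2.99.

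The remaining lists did not pass. The glucocorticoid response list had an adjusted p of 0.716, with Tsc22d3, a glucocorticoid-induced gene, at a log2 fold change of -0.99 (SE 0.33) and Mt2 at -1.27 (SE 0.59). Glucocorticoid and stress receptors had 0.518, with Crhr1 at -0.80 (SE 0.57). Immediate early and heat shock genes had 0.238, with the chaperone genes Hsp90aa1 at -1.06 (SE 0.35) and Hsph1 at -1.02 (SE 0.46). Inflammatory cytokines had 0.932, with Ccl4 at -1.65 and Il1a at 0.85, and the p53 and senescence list had 0.853, with Gdf15 at -1.91 and Phlda3 at -0.68. The adjusted p was 0.726 for adipocytes (Slc2a4 -0.97, Car3 -0.86), 0.674 for thermogenic adipocytes (Cox7a1 -1.38, Elovl3 0.82) and 0.238 for endothelium and mural cells (Egfl7 -0.79, Emcn -0.89). It was 0.853 for Schwann cells (S100b -0.78, Sox10 -0.91), 0.0894 for neutrophils (S100a9 0.76, Camp 0.58) and 0.0776 for red blood cells (Slc4a1 0.61, Alas2 0.55). It was 0.518 for the circadian clock (Bhlhe41 -0.53, Dbp 0.62), 0.431 for oxidative stress (Hmox1 0.68, Srxn1 0.64) and 0.121 for lipid synthesis (Scd1 0.63, Insig1 0.39). It was 0.583 for cytosolic ribosomal proteins (Rps9 -0.40, Rps27a -0.42), 0.557 for histones (Hist1h2bc -0.21, Hist1h3b 0.42) and 0.109 for the sex-linked check (Xist -1.98, Ddx3y -0.60). Median and mean, not taken relative to all genes, and the direction of the test differed in sign for 7 of these. They were lipid synthesis, oxidative stress, circadian clock, histones, cytosolic ribosomal proteins, thermogenic adipocytes and adipocytes. Relative to all genes the medians of these 7 were above 0, as the test pointed. The test pointed down at medians relative to all genes above 0 for glucocorticoid response (0.0085), Schwann cells (0.013) and p53 (0.11).

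Among single genes, 261 were higher and 462 lower at an unadjusted p under 0.05, 2.55% of the 28389 tested where 5% is the chance share. In 1941 genes, 6.84%, the groups did not overlap, where 10% is the chance share. With voom on recovered fragments, a method added after the data were seen, 0 genes passed either way, with 427 higher and 114 lower at an unadjusted p under 0.05. The lowest p belonged to precursors of very short RNAs with 1 to 3 fragments in each library of 1 group and 0 in the other: Mir5620, Mir7236 and Mir27a had them in CRS and Mir1942 in CON. Higher in CRS without passing were the epidermal cytokine gene Il20, at 0.21 ± 0.14 and 1.45 ± 0.31 FPKM, and Serpinb6e, Krtap1-4, Krtap4-6, Klk15 and Snord49b, with log2 fold changes of 2.42, 1.91, 1.81, 1.69 and 2.01. Lower in CRS without passing were the Wnt inhibitor gene Wif1, at 22.6 ± 0.60 and 10.2 ± 2.96 FPKM, and Stmn1, Pclaf, Hmgb2, Ccdc34, Zakit and n-R5s196, with log2 fold changes of -1.14, -1.17, -1.13, -1.38, -1.65 and -2.40.

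The median log2 fold change of all genes was -0.20, with 32.2% of genes higher, and list values are therefore given relative to it. Under median-ratio scaling it was 0.0064 with 50.6% higher, and under quantile normalization -0.024 with 48.0% higher. Of the 35 lists, 15 passed camera, 9 up and 6 down, 0 passed limma's fry (2 at an unadjusted p under 0.05, proliferation and interferon response), and 0 members of any list passed adjusted over all genes or adjusted over the list alone. The other ways of splitting the 6 libraries into 3 and 3 gave 11 to 22 lists, and without CON replicate 1 there were 9. Library medians did not overlap between the groups for hair shaft, proliferation, interferon, sebaceous gland and mitochondrial genome. For any 1 list the chance share of this is 10%, so the lack of overlap alone is no sign of a difference.

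**Figure D3:**
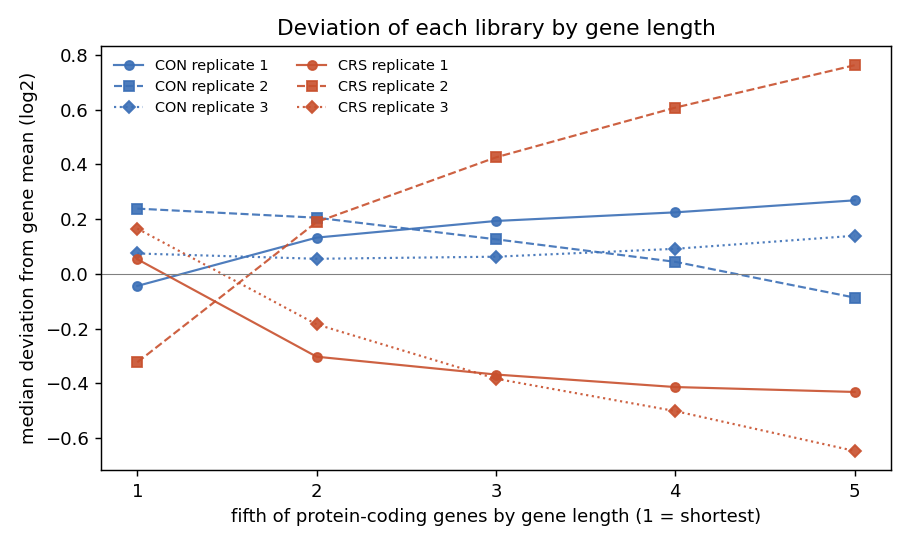
Median deviation of each library from the gene means, in log2 units on the vertical axis, for 5 equal bins of protein-coding genes of at least 1 FPKM, from the shortest to the longest on the horizontal axis. The longest bin lies at 0.76 in CRS replicate 2 and at -0.65 in CRS replicate 3, while the CON libraries lie between -0.087 and 0.27.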

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

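Alternatives added after the data were seen were voom, the length and GC correction, features of at least 200 nt, both outlying libraries left out and the muscle covariate. With limma, 0 genes passed adjusted p 0.05 in every setting run, and with the settings of the comparison itself 0 also passed at 0.1. The smallest adjusted p was 0.0522 with array weights, 0.195 without CRS replicate 2, 0.258 with no trend and 0.333 with both outlying libraries left out. The array weights were 0.66, 0.16 and 5.42 for CRS replicates 1 to 3. The CRS side of every result with array weights therefore rests mostly on CRS replicate 3. At an unadjusted p under 0.05 there were 778 higher and 4098 lower without CRS replicate 2, 1109 and 6525 with array weights, and 122 and 132 without CON replicate 1. The balance of 261 higher and 462 lower was reversed with median-ratio scaling (429 and 178), quantile normalization (490 and 322), voom (427 and 114) and the length and GC correction (780 and 309). A 2-fold change at an unadjusted p under 0.05 gave 242 higher and 288 lower. The length and GC correction moved the share of genes higher from 32.2% to 53.3%. The number of lists that passed, 15, was 0 with an estimated correlation and with fry, and 9 to 23 with each mouse left out, lowest without CON replicate 1 and highest without CRS replicate 2. Over the alternatives, 689 of 904 list results kept their direction and side of the threshold, 76 lost the call, 46 gained one and 93 turned the direction of the test, as did 28 of 2746 for named genes.

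The replicate numbers gave no sign of pairing: same-numbered deviations correlated at -0.12, 0.062 and 0.087. Each library correlated best with one of another number (CON replicate 3 with CRS replicate 1, 0.30). Other differences between the libraries also enter these correlations, so they cannot show that the mice were unpaired. With the replicate block 0 genes and 14 lists passed, the nuclear oxidative phosphorylation list not among them, and the test of inflammatory cytokines turned while their median relative to all genes stayed at -0.063.

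List values are medians relative to all genes and gene values log2 fold changes. For a list, a turn is one of the test's direction: in 44 of the 93 turns the median printed changed sign too, and in 49 it did not. The cause was not tested unless said. The melanocyte list lost its call with a mean FPKM of at least 1 (-0.12), median-ratio scaling (-0.18), voom (-0.12), the muscle covariate (-0.13), an estimated correlation and fry (both -0.20). The direction of the TGF-beta pathway test turned with a mean FPKM of at least 1 (0.090), median-ratio scaling (0.077), quantile normalization (0.10), protein-coding genes (0.044), voom (0.13), the length correction (0.0088) and the muscle covariate (0.48), with which the list passed as higher. It passed as lower with array weights (-0.25) and with both outlying libraries left out (-0.35), as without CRS replicate 2. Tgfbr2 turned with array weights (-0.045) and both outlying libraries left out (-0.13), and Mir17hg with the muscle covariate (0.15).

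Most other turns were of lists and genes that did not pass either way. Lists that turned and passed in the other direction were nuclear oxidative phosphorylation with array weights, higher there and lower in the comparison itself, and cytosolic ribosomal proteins, lower with quantile normalization, the muscle covariate and without CRS replicate 3. Lipid synthesis passed as lower with both outlying libraries left out and without CRS replicate 2, and circadian clock as lower without CRS replicate 2. Turns with pseudocount 0.01 were Hist1h3b (-0.091) and inflammatory cytokines (-0.0063), and with no filter adipocytes (0.10). Those with a mean FPKM of at least 1 were glucocorticoid response (0.038), Schwann cells (-0.0097), inflammatory cytokines (0.062) and p53 (0.21). Median-ratio scaling turned Pmel (0.028), Hist1h2bc (0.035), glucocorticoid response (0.035) and p53 (0.14). Rescaling each library to the same total turned cytosolic ribosomal proteins (0.12), and quantile normalization turned these (-0.34) and inflammatory cytokines (-0.021). Array weights turned Hist1h2bc (0.11), Rps9 (0.054), Rps27a (0.46), circadian clock (-0.11), inflammatory cytokines (0.055), lipid synthesis (0.13) and nuclear oxidative phosphorylation (0.40). Protein-coding genes alone turned inflammatory cytokines (-0.060), and ranks p53 (0.11). Fry, which compares with no other genes, turned only the direction of the test, at unchanged medians, for circadian clock (0.13), adipocytes (0.17), thermogenic adipocytes (0.060), oxidative stress (0.095), cytosolic ribosomal proteins (0.094) and histones (0.15). Voom turned Pmel (0.025), Hist1h2bc (0.032), glucocorticoid response (0.10), Schwann cells (0.10), inflammatory cytokines (0.033), p53 (0.18) and immediate early genes (0.030). The length correction turned p53 (0.055) and cytosolic ribosomal proteins (0.035).

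With both outlying libraries left out, the genes that turned were Mitf (-0.16), Ms4a2 (-0.040), Mcpt4 (-0.11) and Rps27a (0.096). The lists were circadian clock (-0.25), adipocytes (-0.14), fibroblasts (0.0097), macrophages (0.031), mast cells (-0.082), lipid synthesis (-0.20) and nuclear oxidative phosphorylation (0.20). The muscle covariate turned Kit (0.090), H2-Eb1 (-0.010), Cd3g (-0.00018), Cma1 (-0.097), S100a9 (-0.50), Camp (-0.090), Crhr1 (0.00079), Hist1h3b (-0.53), Slc2a4 (0.35) and Car3 (0.16). Among lists it turned melanocyte-directed signals (0.21), glucocorticoid response (0.29), stress receptors (0.12), hair matrix (0.032), thermogenic adipocytes (0.019), muscle itself by construction (0.013), endothelium (0.31), Schwann cells (0.32), neutrophils (0.024), p53 (0.23), immediate early genes (0.080), cytosolic ribosomal proteins (-0.92), red blood cells (-0.62), histones (-0.42) and sex-linked genes (0.054).

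Besides the melanocyte list, calls were lost as follows, at unchanged direction of the test. The mast cell and follicle stem cell lists lost theirs with pseudocount 1, no filter, quantile normalization, array weights, the length correction and the muscle covariate, mast cells also with no trend, and follicle stem cells with ranks and with both outlying libraries left out. With both outlying libraries left out the follicle stem cell median changed sign, to -0.052. Nuclear oxidative phosphorylation lost its call with a mean FPKM of at least 1, median-ratio scaling, no trend, protein-coding genes, voom and the length correction. The mitochondrial genome list lost its call with array weights (-0.72), both outlying libraries left out (-0.54) and the muscle covariate (-0.55), and T, NK and B cells with both outlying libraries left out (0.31). With the muscle covariate the activated keratinocyte (0.32), macrophage (0.087) and T, NK and B cell (0.11) lists also lost theirs, so that the 7 that kept their calls were hair shaft, epidermis, sebaceous gland, fibroblasts, interferon, proliferation and nuclear oxidative phosphorylation.

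Calls were gained by lists that had not passed. Hair matrix passed as lower with no filter (-0.31), array weights (-0.35), the length correction (-0.23) and both outlying libraries left out (-0.58), and melanocyte-directed signals with array weights (-0.42) and both outlying libraries left out (-0.53). Lipid synthesis passed as higher with a mean FPKM of at least 1, median-ratio scaling, voom, the length correction and the muscle covariate, and neutrophils with pseudocount 0.01, ranks and voom. Red blood cells passed as higher with a mean FPKM of at least 1, array weights and protein-coding genes, and circadian clock and adipocytes with the muscle covariate. Endothelium passed as lower and cytosolic ribosomal proteins as higher with array weights and with both outlying libraries left out, sex-linked genes as lower with the former, and Schwann cells, p53 and immediate early genes as lower with the latter.

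With each mouse left out in turn, the melanocyte list ran from -0.44 to -0.070 and TGF-beta from -0.43 to 0.34. Turning lists ran as follows: glucocorticoid response -0.091 to 0.17, stress receptors -0.30 to 0.015, circadian clock -0.28 to 0.34, adipocytes -0.14 to 0.55, thermogenic adipocytes -0.093 to 0.27 and endothelium -0.77 to 0.014. Schwann cells ran from -0.17 to 0.21, macrophages 0.10 to 0.84, neutrophils 0.031 to 0.83, inflammatory cytokines -0.27 to 0.12, p53 -0.25 to 0.28 and oxidative stress -0.056 to 0.31. Immediate early genes ran from -0.22 to 0.14, lipid synthesis -0.18 to 0.38, nuclear oxidative phosphorylation -0.49 to 0.14, cytosolic ribosomal proteins -0.37 to 0.83, red blood cells -0.42 to 0.65 and histones -0.23 to 0.83. Among genes, Hist1h3b ran from -0.26 to 1.22, Rps9 from -0.67 to 0.076 and Rps27a from -0.95 to 0.30. Depth limits Mir5620, Mir7236, Mir27a and Mir1942, which rest on 1 to 3 fragments per library of 1 group. It also limits Snord49b, with 1 fragment per CON library and 3 to 14 per CRS library, and Hist1h3b, with 0 to 8 per library.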

Other observations

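Gene families were grouped by symbol root and tested after the results were seen, 225 families of at least 10 tested members. The high mobility group family, chromatin proteins abundant in dividing cells, was lower in 11 of its 12 members, pseudogenes and related sequences included, with a median log2 fold change of -0.98 (camera adjusted p = 2.10e-05; p = 0.0062 and adjusted p = 0.986 with an estimated correlation). Hmgb2 was 87.0, 97.3 and 70.0 FPKM in CON and 29.5, 45.6 and 42.3 FPKM in CRS, and Hmgb1 was 63.1, 55.9 and 54.6 FPKM in CON and 24.0, 36.3 and 28.6 FPKM in CRS. Besides Hmgb1, Hmgb2 and Hmgb3, all members were pseudogenes or related sequences of Hmgb1. Fragments shared between Hmgb1 and these leave the single members uncertain. The member count and the family test are uncertain too, because they may count Hmgb1 repeatedly. The Klk family of kallikrein-related proteases, the pseudogenes Klk1b7-ps and Klk1b10-ps included, was higher in 13 of 16 members (median 0.60, camera adjusted p = 5.77e-09; p = 0.0472 and adjusted p = 0.986 with an estimated correlation). Klk6 was 6.71, 17.5 and 14.5 FPKM in CON and 32.1, 32.2 and 27.7 FPKM in CRS. The Serpina family was higher in 15 of 15 members (median 0.54, camera adjusted p = 7.84e-09; p = 0.0222 and adjusted p = 0.986 with an estimated correlation), its members Serpina3j and Serpina3b having near-identical relatives. Most of its members were Serpina3 genes, the pseudogene Serpina3e-ps included, so its count and test may also count shared fragments repeatedly. The Krtap family was higher in 57 of 57 members, with a median of 1.41 (camera adjusted p = 1.23e-50; p = 0.0443 and adjusted p = 0.986 with an estimated correlation). Its library medians overlapped, with CRS replicate 2 at -0.067 and CON replicate 2 at 0.26, CON replicate 1 lay at -1.73, and 2 of the 10 splits, the real one included, gave a difference as large.

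Chosen after the results were seen were the tests of gene length, hair matrix and immune cells, and the splits for lists. The split for genes and the tests of hair follicle content and of muscle or fat were written before. The bounds of the hair matrix, immune cell and length tests and the application of the muscle test were revised after results were seen. Earlier versions used 2 SE, a merged immune list and the extreme lists picked from the data, and they had excluded hair matrix, immune cells and muscle, which the versions used here leave open.

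The first pattern is the fall of the proliferation and interferon lists. After subtracting each library's trend over gene length and GC content, the difference of library medians between CRS and CON was -0.57 (SE 0.12) for proliferation and -0.53 (SE 0.13) for interferon, and relative to all genes the medians were -0.61 and -0.48, so that this trend was not the whole cause. Less hair matrix in the CRS skin stays open, because the hair matrix list moved 0.45 above proliferation (SE 0.17), with a 95% interval from -0.025 to 0.93. Fewer immune cells stay open too, because the macrophage list moved 1.04 above interferon (SE 0.57, interval -0.54 to 2.63) and the T cell list 1.03 (interval -0.093 to 2.15). Of the 10 splits of the libraries, 1, the real one, gave a difference as large for proliferation (0.815, highest other 0.725) and 1 for interferon (0.788, highest other 0.674). The library medians of both lists did not overlap between the groups, so the real split had to give the largest difference. The count therefore adds nothing to that lack of overlap. Also, 10 splits are too few for a share under 0.05, and an effect of stress may be stated only as an untested hypothesis.

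The second pattern is the change of the melanocyte and melanogenesis list. Different hair follicle content may contribute and cannot be told apart from it: the hair shaft list moved by 0.988 (SE 0.55), the opposite way, and the hair matrix list by -0.36 (SE 0.35), the same way. The length trend stays open as well. The list's difference, not taken relative to all genes, was -0.35 (SE 0.26) before and -0.18 (SE 0.09) after the correction, with a camera adjusted p of 0.0141 after it. Relative to all genes its median went from -0.20 to -0.16.

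The third pattern is the number of lists that passed, which was 15 for the real groups and 22 for the highest other split. Of the 10 splits, 7, the real one included, gave at least as many. The count of 15 therefore does not set the real groups apart and is no sign of a difference between CRS and CON. For genes the real count was 0, the highest other 1, so that all 10 splits had to give as many and this test says nothing about chance. Splits with CON replicate 1, CRS replicate 2 and either of 2 CON mice on 1 side had 4059 and 4130 genes at an unadjusted p under 0.05 against 723, and the split of CON replicates 1 and 3 with CRS replicate 1 had 3062, which points to a structure of the libraries. A different share of muscle or fat in the skin pieces cannot be told apart from the groups: the muscle median, not taken relative to all genes, was -2.01 and the adipocyte median -0.026, and 7 of 10 other cell type lists moved the other way while endothelium, Schwann cells and melanocytes did not (relative to all genes muscle was -1.81, adipocytes 0.17 and Schwann cells 0.013, which then moved the other way). With the muscle covariate 12 lists passed, 7 of the 15 as before and 5 others.

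Libraries differed in other measures. Spearman correlation across 11781 protein-coding genes between a library's deviation and gene length, genes not being independent replicates, was 0.23, -0.43 and 0.12 in CON replicates 1 to 3 and -0.33, 0.54 and -0.54 in the CRS replicates. The cytosolic ribosomal protein median of CRS replicate 2 was -1.53, against -0.32 to 0.72 in the others. Xist was 2.80 FPKM, from 951 fragments, in CON replicate 1 and 0.022 to 0.17 FPKM in the other libraries. The Y-linked genes Ddx3y, at 8.68 to 32.7 FPKM, and Eif2s3y, at 14.6 to 24.1 FPKM, were expressed in all 6, so each library held male RNA. Whether CON replicate 1, with 15.3% mitochondrial fragments, was RNA of 1 mouse and of the same kind of skin piece is therefore open, and list values resting on it share that doubt. Of the 50 genes with the lowest p, 25 were under 200 nt, as were 7.63% of all tested, with a median of 9 fragments summed over the 6 libraries.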
